A study of Mus musculus with 12 samples.

How the data were processed

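RNA of 6 spontaneous lung tumours and 6 normal lungs of untreated B6C3F1 mice aged 2 years was hybridised to Affymetrix mouse arrays, 1 array per sample, as biotin-labelled product of a one-cycle protocol per the labels. Groups and replicate numbers came from the sample titles. The labels do not say that the samples are separate animals, so p-values measure the spread between these samples.

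The deposited values are signal intensity per probe set on a linear scale, made with MAS5 per the submitters' processing notes; its version and settings were not given in the sources used here. A check of the values found the same 2% trimmed mean on every array and no missing values, so the authors' global scaling was kept and no further normalization was applied. Such scaling does not equalise the distributions: the median signal was 160.0 ± 5.27 in normal lungs and 138 ± 8.22 in tumours (SD, n = 6 each; exact permutation p = 0.00216, Benjamini-Hochberg adjusted over 5 array measures 0.0108). Detection calls were not used here, and 13.4% of probe sets in normal lungs and 15.1% in tumours lay under the offset. The 3' to 5' signal ratio of actin was 1.17 and 1.20 (exact permutation p = 0.104). Correlations between arrays on the log2 scale were 0.932 to 0.966 among normal lungs, 0.907 to 0.954 among tumours and 0.868 to 0.919 between the groups, and no arrays were duplicates.

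The table held 45101 probe sets, of which 64 array controls were left out. Gene symbols came from the platform annotation held by GEO, checked through gene identifiers against mouse RefSeq tables (assembly GRCm38.p6). Of 45037 probe sets tested, 34945 had 1 symbol, 932 several and 9160 none listed. No symbol changed. The 18193 genes were each represented by the probe set with the highest mean over all arrays.

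Values were transformed as log2(signal + 16), which shrinks differences of dim probe sets, and fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend; 6 against 6 arrays, no covariate). Benjamini-Hochberg adjustment ran over all 45037 probe sets with a threshold of 0.05, two-sided. Counts of genes also required a log2 difference of 1. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.

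Before the data were examined, 49 gene lists were fixed from general knowledge, covering cell types of the lung, signalling and metabolic processes, handling of tissue and sex-linked genes. Lists were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. fry was run beside it: its PValue tests whether members move, on balance, one way, and PValue.Mixed whether they change in either direction. The fry result is given where it and camera fell on different sides of the threshold. Many list members are correlated, and camera at the preset correlation called up to 27 lists in other splits of the arrays, so list calls rest also on the counts of members. The named genes were fixed by a rule: the 12 largest rises and 12 largest falls among genes with a single symbol past the threshold, whose brighter group lies above the median of all probe sets and whose arrays do not overlap; in each list up to 4 members with the smallest adjusted p, and any other member whose value is given; and fixed genes whatever their result. List members beyond those 4, and the genes given per array in the closing section, were chosen after their values were seen.

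The fit was tested on simulated data with the real means and spreads and 200 changed probe sets among 45037. These simulated arrays held independent noise. It recovered 83.3% of changes of 2 log2 units, 16.4% of changes of 1 and 5.97% of changes of 0.5, and called 3 unchanged probe sets. Recovery depends on how many probe sets change, here few, so it bounds the real case loosely.

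Alternatives were the offset, quantile normalization, median centring, a filter on dim probe sets, no intensity trend, array and group weights, the replicate number as a block, other ways to represent a gene, the estimated correlation, and leaving out each array. Groups, tests, lists and these alternatives were set before the data were examined. Settings without normal lungs 2 and 4, without the 4 tumours with Eif2s3y, and with Eif2s3y as a covariate were added after seeing the data.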

Results

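Gene expression was measured in lung tissue of aged B6C3F1 mice, the cross of C57BL/6 females and C3H males used in long-term rodent bioassays. The groups were 6 lung tumours that arose spontaneously in untreated animals and 6 normal lungs, 1 array each, all from mice of 2 years. Per array, the median signal ranged from 152 to 165 in normal lungs and from 127 to 150 in tumours. The number of arrays limits the precision, and the labels do not say whether the samples are separate animals. Differences below are tumour minus normal lung on the log2(signal + 16) scale, given as the difference ± its standard error with n = 6 arrays per group. Adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

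Most marker genes of the lung's vessels, cilia and muscle were lower in spontaneous tumours than in normal lung, and many genes of epithelial junctions, the cell cycle, glycolysis and alveolar macrophages were higher. Cldn2, a claudin of leaky epithelia that forms cation pores, rose most of the genes whose groups do not overlap, from 53.01 ± 33.2 to 5581 ± 4634 signal units (SD, n = 6), a difference of 6.16 ± 0.44 (adjusted p = 2.87e-07). Slc6a2, the noradrenaline transporter, fell most of these, from 4239 ± 2311 to 133 ± 217 (SD, n = 6), a difference of -5.60 ± 0.62 (adjusted p = 9.80e-06). In all, 846 genes were at least 2-fold higher and 1911 at least 2-fold lower, with 185 and 666 of them beyond 4-fold. Among 18193 genes, 2201 passed the threshold upwards and 3158 downwards. Arrays of the groups did not overlap for 3353 genes (18.4%), where chance gives 0.216%.

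Counted by probe set, 4529 of 45037 were higher and 6279 lower, so that 41.9% of the calls were higher in tumours. This split depended on scaling, being 50.6% after quantile normalization and 61.9% after centring each array on its median. The median difference over all probe sets moved from -0.06 to 0.05 and 0.13 under these scalings, and smaller differences are relative to that shift. All 2757 genes called 2-fold kept their sign under both scalings. For 39 genes another probe set passed the threshold in the opposite direction.

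Sex-linked transcripts were not balanced between the groups. Xist, the RNA that silences an X chromosome in females, was at 7877 or more in all 6 normal lungs and in tumours 4 and 6, and at 109 or less in tumours 1, 2, 3 and 5. Eif2s3y, a Y-linked gene, was at 740 or more in those 4 tumours and at 27.4 or less elsewhere. Of the 4 measured sex-linked genes 3 rose, Eif2s3y (3.42 ± 1.04), Kdm5d and Uty (1.52 ± 0.52), and Xist fell (-4.46 ± 1.24). The list's median was 2.26, and 3 rose and 1 fell when adjusted over the list alone. The set tests gave camera adjusted p = 0.197 and fry adjusted p = 0.0206 upwards. The calls of the 3 rises could be lost with 1 array: leaving out 1 array gave adjusted p up to 0.0595 for Eif2s3y, 0.508 for Kdm5d and 0.101 for Uty. The Eif2s3y call was lost without normal lung 1 or 2 or tumour 1, 2, 3 or 5, the Kdm5d call without any of tumours 1 to 5, and the Uty call without any array but tumours 4 and 6. On the Kdm5d probe set of the main fit tumour 4 was at 24.01, against 458.1 or more in tumours 1, 2, 3 and 5. The loss of the Kdm5d call without tumour 4 therefore reflects another probe set becoming the brightest, not a smaller rise. With the log2 signal of Eif2s3y as a covariate, chosen after seeing the data, the count of probe sets higher in tumours was 2603 and that of probe sets lower in tumours 4069. All 2757 genes called 2-fold kept their sign in that fit and 2128 stayed past the threshold.

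The 12 largest rises also included Arg1 and Mmp12. Arg1, an arginase of the urea cycle and of alternatively activated macrophages, rose from 128 ± 127 to 5982 ± 4868 (5.27 ± 0.52), and Mmp12, the macrophage elastase, rose from 123 ± 83.7 to 3067 ± 2567 (4.28 ± 0.42). Others were Kng1 (4.92 ± 0.77), a kininogen, Bcl2l15 (4.06 ± 0.36), Ivl (3.98 ± 0.71), a protein of the cornified envelope, and Egln3 (3.91 ± 0.47), an oxygen-sensing hydroxylase. The rest of the 12 were Cxcl3 (3.81 ± 0.49), S100a14 (3.78 ± 0.55), Ereg (3.67 ± 0.54), an ErbB ligand, Klk13 (3.65 ± 0.65) and Sox9 (3.61 ± 0.53), a transcription factor of the distal lung bud. Adjusted p-values of these 12 ranged from 2.87e-07 to 7.48e-04. Kng1 is made mainly in liver, and normal lungs 2 and 4, which also carried the liver transcripts described under the other observations, had Kng1 signals of 574 and 383 against 38.4 or less in the other 4.

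The 12 largest falls also included Tmem100 and Mfap4. Tmem100, an endothelial membrane protein, fell from 9007 ± 1419 to 402 ± 674 (-5.43 ± 0.55), and Mfap4, a protein of elastic fibres, fell from 13039 ± 3080 to 619 ± 790 (-5.32 ± 0.74). Genes of the cardiac muscle list were among them, with Myh6 (-5.18 ± 0.67), Actc1 (-4.94 ± 0.49) and Myl7 (-4.93 ± 0.46). Hpgd, which degrades prostaglandins, fell from 17482 ± 2991 to 906 ± 1066 (-4.92 ± 0.51). The remaining genes were Pcolce2 (-5.05 ± 0.62), Ogn (-4.92 ± 0.58), Alas2 (-4.81 ± 0.70), the erythroid haem synthase, Pon1 (-4.81 ± 0.35) and Mapt (-4.72 ± 0.31). Adjusted p-values of the 12 falls ranged from 1.43e-07 to 1.21e-04.

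**Figure D1:**
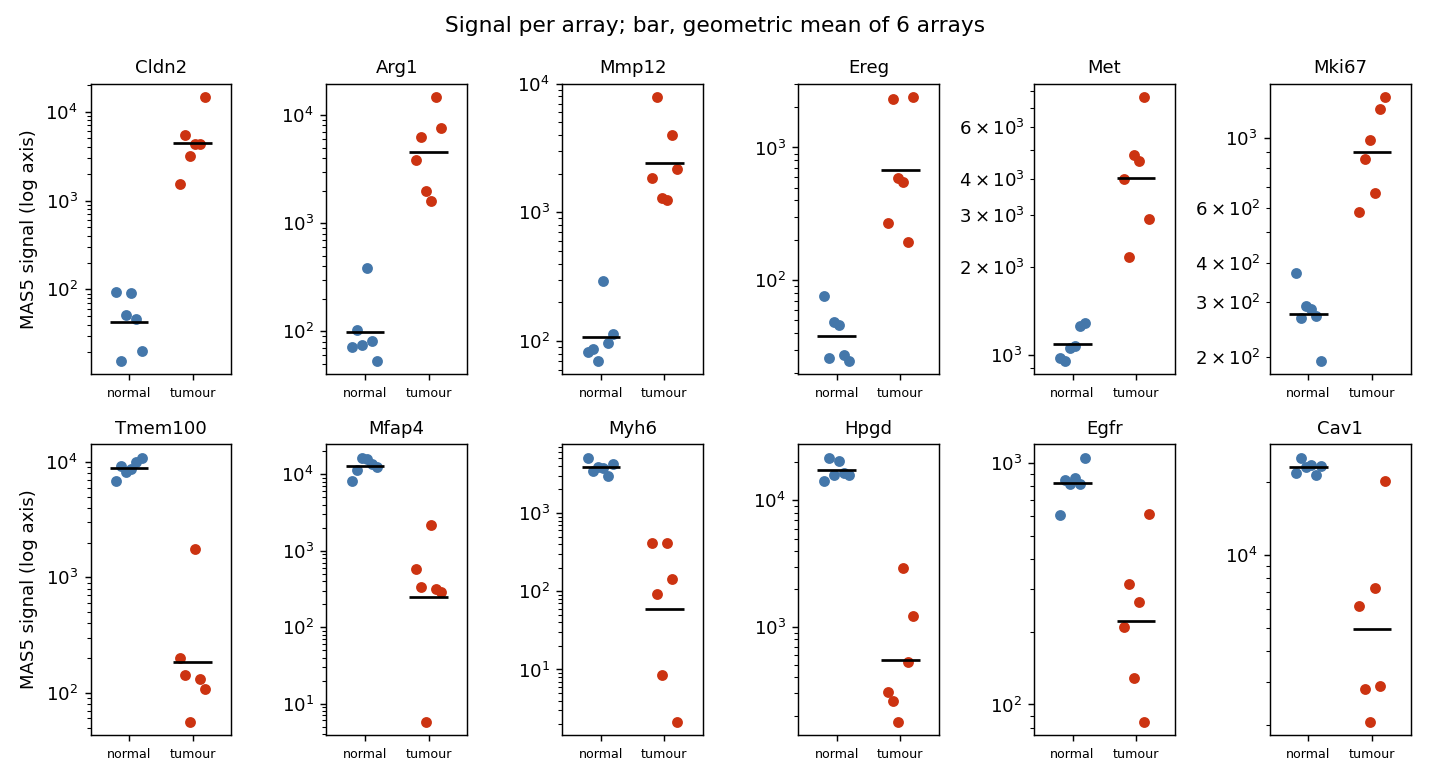
MAS5 signal of 12 genes on each array, on a log axis, with normal lungs in blue and tumours in red and a bar at the geometric mean of 6 arrays. The groups do not overlap for Cldn2, where normal lungs lie between 15.7 and 93.4 and tumours between 1549 and 14640, and overlap for Egfr, where tumour 6 lies at 611 and normal lung 1 at 606.

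Markers of vessels and of both muscle lists were lower in every tumour than in every normal lung, taken as list means. Of 24 endothelial genes 23 fell, among them Gpihbp1 (-2.63 ± 0.13), which anchors lipoprotein lipase to capillaries, Acvrl1 (-3.63 ± 0.20), Eng (-2.85 ± 0.16) and Ramp2 (-3.82 ± 0.23). The members' median was -2.83, and 23 fell when adjusted over the list alone, with camera adjusted p = 2.47e-20, and adjusted p = 0.145 with an estimated correlation. Only Aplnr missed the threshold (-0.64 ± 0.32). All 11 smooth muscle genes fell, with Myh11 (-3.86 ± 0.22), Tagln (-2.45 ± 0.25) and Acta2 (-1.65 ± 0.20). For this list the median was -2.44, 11 fell when adjusted over the list alone, and the set test gave camera adjusted p = 1.81e-08, and adjusted p = 0.145 with an estimated correlation. Of 14 genes of the cardiac muscle that sheathes mouse pulmonary veins, 13 fell, including Myoz2 (-3.42 ± 0.22), Pln (-2.81 ± 0.20) and Tnni3 (-4.16 ± 0.30). These members had a median of -3.49, and 13 fell when adjusted over the list alone, with camera adjusted p = 1.27e-09, and adjusted p = 0.148 with an estimated correlation.

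Most stromal and surface lining markers were also lower. Fibroblast and interstitial genes fell in 14 of 19 cases, with Col13a1 (-3.80 ± 0.28) and Tcf21 (-4.52 ± 0.43), a transcription factor of lung mesenchyme. In this list 2 rose and 16 fell when adjusted over the list alone, with a median of -1.97, and the set test gave camera adjusted p = 3.55e-06, and adjusted p = 0.252 with an estimated correlation. The 2 that rose were the collagens Col1a1 (0.95 ± 0.34) and Col3a1 (0.65 ± 0.24). Over all probe sets they did not pass (adjusted p = 0.059 and 0.0661), but 1 of the 2 probe sets of each did, upwards. Col1a2 did not pass either (0.12 ± 0.24), though 1 of its 3 probe sets rose. Mesothelial genes fell in 5 of 9 cases, with Gpm6a (-4.42 ± 0.42) and Rspo1 (-3.13 ± 0.31). Across the list the median was -1.997, and 6 fell when adjusted over the list alone, with camera adjusted p = 0.00818, and adjusted p = 0.292 with an estimated correlation. Zeb1 (-2.21 ± 0.17), Cdh11 (-2.40 ± 0.26) and Snai2 (-2.57 ± 0.29) were among 8 of 13 mesenchymal transition genes that fell. The set test gave camera adjusted p = 0.00455, and adjusted p = 0.265 with an estimated correlation, the median was -0.81, and 8 fell when adjusted over the list alone.

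Among epithelial types, ciliated, type I and most club cell genes fell and several type II genes rose. Of 17 ciliated genes 16 fell, with Hydin (-2.19 ± 0.18), Tppp3 (-3.79 ± 0.31) and Foxj1 (-2.79 ± 0.39), the master regulator of motile cilia. Members had a median difference of -2.68, 16 fell when adjusted over the list alone, and the set test gave camera adjusted p = 1.71e-11, and adjusted p = 0.148 with an estimated correlation. Type I genes, of the flat cells of gas exchange, fell in 15 of 17 cases, with Scnn1g (-2.66 ± 0.26), Igfbp2 (-3.57 ± 0.35) and Hopx (-2.35 ± 0.23). The members' median was -1.42, and 15 fell when adjusted over the list alone, with camera adjusted p = 3.42e-07, and adjusted p = 0.148 with an estimated correlation. Cav1, a protein of caveolae, fell (-2.20 ± 0.42), as did Ager (-1.01 ± 0.27). Club and secretory genes were split, 9 of 14 falling, with Cyp4b1 (-4.03 ± 0.35), and 3 rising. The risers, which encode secreted mucosal proteins, were Bpifa1 (5.94 ± 1.07), Muc5b (2.50 ± 0.60) and Scgb3a1 (2.90 ± 0.90). For this list the median was -2.25, 3 rose and 10 fell when adjusted over the list alone, and the set test gave camera adjusted p = 0.0149, and adjusted p = 0.308 with an estimated correlation. The Scgb3a1 call was lost without normal lung 3, 5 or 6 or tumour 1, 2, 4 or 5, with adjusted p up to 0.0666.

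Type II genes, of the surfactant-making cells, rose in 8 of 20 cases, with Muc1 (1.36 ± 0.20), Cebpa (1.597 ± 0.36) and Napsa (1.37 ± 0.35). These members had a median of 0.62, and 9 rose when adjusted over the list alone, with camera adjusted p = 0.00135, and adjusted p = 0.472 with an estimated correlation. In the fry test the type II list did not pass (adjusted p = 0.0902). Under settings chosen after seeing the data fewer type II genes rose: 4 without normal lungs 2 and 4, 3 without the tumours with Eif2s3y (median 0.27) and 1 with Eif2s3y as a covariate (median 0.35). The count was 6 after quantile normalization and 11 after median centring. Sftpc itself (-0.33 ± 0.18, adjusted p = 0.219) and Nkx2-1 (0.20 ± 0.23, adjusted p = 0.603) did not pass, although the mean of the probe sets of Sftpc fell. Nkx2-1 differed between tumours, at 228.1 and 223.4 in tumours 2 and 6, below the 260.2 to 381.8 of normal lungs. It was at 588.3 and 559.8 in tumours 3 and 5, and at 378.4 and 410.3 in tumours 1 and 4. Sftpc signals, 31270 to 55870, lie near the top of each array's range, where a further rise would be hard to see. Scgb1a1, the club cell secretoglobin, fell (-0.92 ± 0.28, adjusted p = 0.0263), a call lost without normal lung 1, 3 or 4 or tumour 6, with adjusted p up to 0.0554, and also under quantile normalization and median centring. Scgb1a1 was the brightest gene on 5 of 6 normal lungs, at the top of the scale, so the size of its difference is not exact.

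Tumours differed among themselves in type II and gastric genes. Mean log2 signals of the type II list in tumours 2 and 6 were 12.33 and 12.12, against 13.62 to 13.92 in the other tumours and 12.44 to 12.68 in normal lungs. Their means of the gastric and intestinal list were 9.37 and 9.78, against 6.54 to 8.07 in the other tumours and 5.90 to 6.78 in normal lungs. Of its 16 genes 6 rose in tumours as a group, with Cldn2 (6.16 ± 0.44), Gkn2 (5.05 ± 1.004), a gastrokine, and Ctse (3.56 ± 0.76), a gastric protease. In this list 6 rose when adjusted over the list alone, with a median of 1.48, and the set test gave camera adjusted p = 0.00284, and adjusted p = 0.308 with an estimated correlation.

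**Figure D2:**
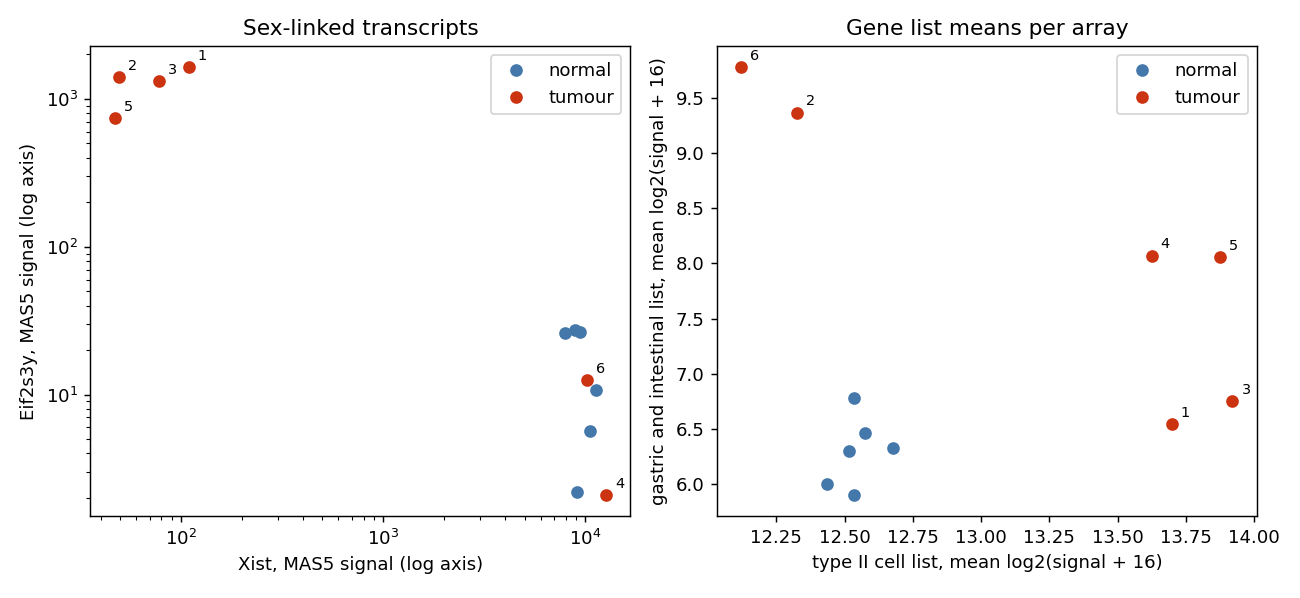
Left, signals of Xist and Eif2s3y on each array, both on log axes; right, the mean log2(signal + 16) of the type II and of the gastric and intestinal lists, with tumours numbered. Tumours 1, 2, 3 and 5 carry Eif2s3y at 740 or more, and tumours 2 and 6 reach gastric list means of 9.37 and 9.78.

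Many genes of the alveolar macrophage list rose, and lymphocyte lists had members that fell and none that rose. Alveolar macrophage genes rose in 8 of 14 cases, with Pparg (2.46 ± 0.31), their lineage regulator, Atp6v0d2 (2.01 ± 0.36) and Cd68 (1.73 ± 0.34). The 6 members that did not pass were Marco (1.45), Siglecf (0.98), Chil3 (0.94), Fabp1 (0.78), Krt79 (0.71) and Lpl (-0.24). Their adjusted p-values ranged from 0.118 to 0.553. Across the list the median was 1.08, and 8 rose when adjusted over the list alone, with camera adjusted p = 7.46e-05, and adjusted p = 0.252 with an estimated correlation. Of 13 other macrophage and monocyte genes 5 rose, with Cd14 (2.22 ± 0.31) and the complement gene C1qa (1.36 ± 0.23), and 2 fell, including Cd163 (-2.21 ± 0.46). The set test gave camera adjusted p = 0.0111, and adjusted p = 0.345 with an estimated correlation, the median was 0.59, and 7 rose and 3 fell when adjusted over the list alone. Natural killer genes fell in 5 of 10 cases, with Gzma (-2.93 ± 0.38). Members had a median difference of -0.85, 5 fell when adjusted over the list alone, and the set test gave camera adjusted p = 0.0186, and adjusted p = 0.433 with an estimated correlation. T cell genes fell in 3 of 14 cases, with Cd28 (-1.04 ± 0.22). This is near the share over all genes, of which 3158 of 18193 fell. Of the 14, 6 were no brighter than the median probe set in either group. The members' median was -0.70, and 3 fell when adjusted over the list alone, with camera adjusted p = 0.0186, and adjusted p = 0.308 with an estimated correlation. B and plasma cell genes fell in 5 of 13, with Cr2 (-1.50 ± 0.34). For this list the median was -0.76, 6 fell when adjusted over the list alone, and the set test gave camera adjusted p = 0.0344, and adjusted p = 0.472 with an estimated correlation. With Eif2s3y as a covariate 4 alveolar macrophage genes rose, and 3 natural killer and 1 B and plasma cell gene fell. Without normal lungs 2 and 4, 2 genes fell in each of the natural killer, T cell and B and plasma cell lists. Without the tumours with Eif2s3y, 6 T cell, 4 natural killer and 1 B and plasma cell gene fell. After quantile normalization and after median centring 3 natural killer, 2 T cell and 3 B and plasma cell genes fell. Tumour 2 stood apart, with T cell and natural killer means of 7.71 and 7.99, within the normal range, where the other 5 tumours lay below every normal lung. Its alveolar macrophage mean was 10.46, below the highest normal lung at 10.67. The set test of the B and plasma cell list was lost without normal lung 4 or tumour 2, 3 or 5.

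The neutrophil list had 1 of 11 members higher and 0 lower (median -1.12, camera adjusted p = 0.746), the riser being Lcn2 (2.999 ± 0.59). Normal lung 1 had a neutrophil list mean of 13.51 against 9.67 in the next normal lung, and without it the median of the neutrophil list was -0.05. The erythroid list had 0 of 5 members higher and 2 lower (median -0.16, camera adjusted p = 0.631). The adipocyte list had 1 of 7 members higher and 2 lower (median -0.75, camera adjusted p = 0.369, fry adjusted p = 0.048 downwards). Fabp4, a fatty acid carrier also made by macrophages, was the riser (2.51 ± 0.46). Normal lung 2 had an adipocyte list mean of 8.35 against 6.99 in the next normal lung; without normal lungs 2 and 4, 1 adipocyte gene was lower (median -0.48), and without the tumours with Eif2s3y 0 were (median -0.49). The neuroendocrine list had 0 of 10 members higher and 2 lower (median -0.04, camera adjusted p = 0.631, fry adjusted p = 0.0104 downwards). The basal list had 1 of 10 members higher and 0 lower (median -0.15, camera adjusted p = 0.746), and its camera direction was up although the median was negative. The MHC class II list had 0 of 9 members higher and 1 lower (median 0.28, camera adjusted p = 0.521).

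**Figure D3:**
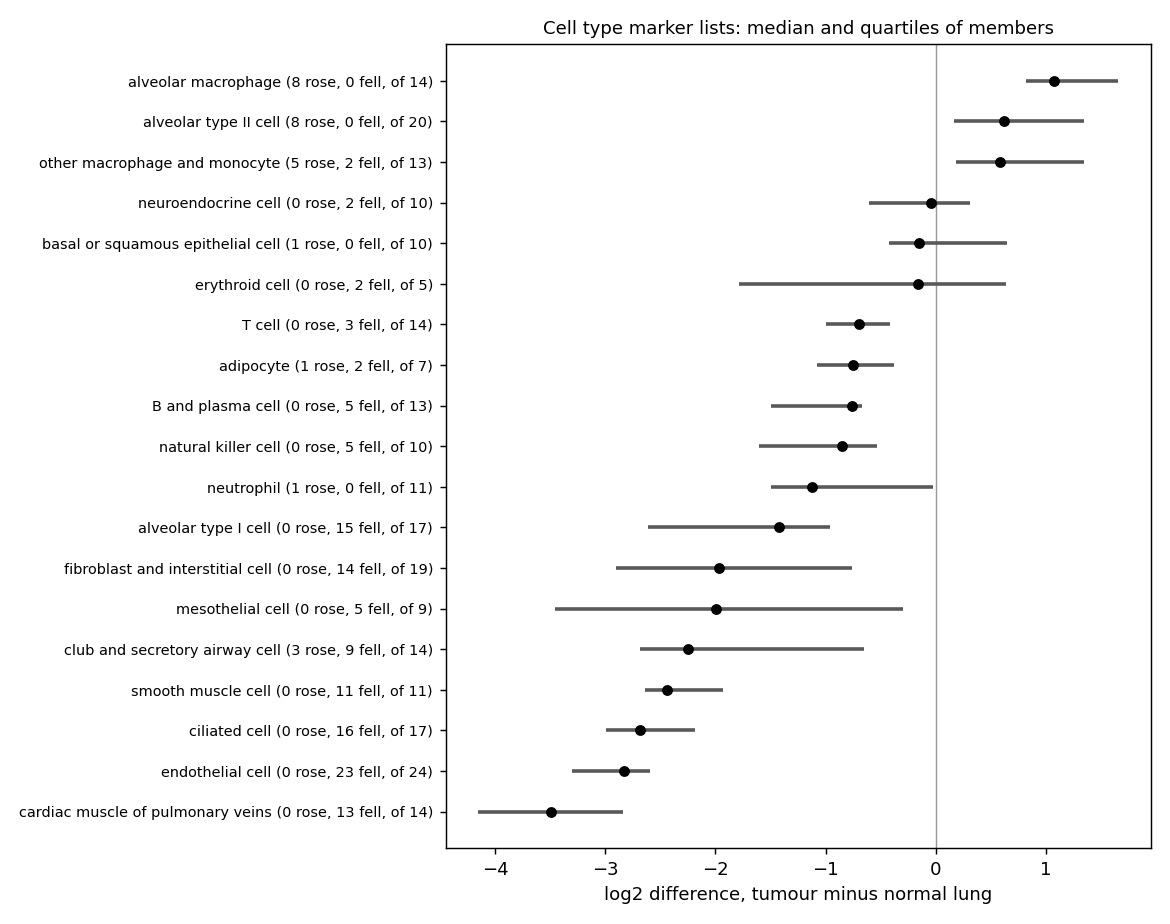
Median (point) and quartiles (line) of the log2 differences of the measured members of each cell type list, tumour minus normal lung, 6 arrays each. The lowest median is that of cardiac muscle at -3.49 and the highest that of alveolar macrophages at 1.08.

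Proliferation and glycolysis genes rose together. Of 32 cell cycle genes 25 rose, with Bub1b (2.71 ± 0.31), a mitotic checkpoint kinase, Mki67 (1.67 ± 0.21) and Mcm7 (1.27 ± 0.17), and none fell. These members had a median of 1.33, and 28 rose when adjusted over the list alone, with camera adjusted p = 2.00e-14, and adjusted p = 0.155 with an estimated correlation. Of 15 glycolysis genes 11 rose, with Hk2 (2.17 ± 0.16), hexokinase, Aldoc (2.42 ± 0.20) and Ldha (1.92 ± 0.18), lactate dehydrogenase. In this list 12 rose when adjusted over the list alone, with a median of 1.53, and the set test gave camera adjusted p = 3.59e-09, and adjusted p = 0.148 with an estimated correlation. Of 16 hypoxia response genes 7 rose, with Hif1a (1.34 ± 0.13), and 4 fell, with Vegfa (-0.86 ± 0.17). Across the list the median was 0.79, and 8 rose and 4 fell when adjusted over the list alone, with camera adjusted p = 0.0111, and adjusted p = 0.363 with an estimated correlation. Both without normal lungs 2 and 4 and with Eif2s3y as a covariate 6 rose and 1 fell. The list mean exceeded the mean of normal lungs by 0.98, 0.94 and 1.46 in tumours 2, 3 and 6, and by only 0.20 and 0.14 in tumours 1 and 4, with no rise in tumour 5. Respiratory chain genes rose in 12 of 24 cases, with Uqcrc2 (0.71 ± 0.11). The set test gave camera adjusted p = 1.20e-05, and adjusted p = 0.265 with an estimated correlation, the median was 0.36, and 15 rose when adjusted over the list alone. This count depended on scaling, with 8 rising and 1 falling after quantile normalization (median 0.24) and 18 rising after median centring (median 0.55). With Eif2s3y as a covariate 6 rose.

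Genes that report Ras-MAPK signalling rose as a group. Of 17 measured, 10 rose, among them Dusp4 (2.82 ± 0.23), a phosphatase that restrains ERK, Spred1 (1.64 ± 0.18), Epha4 (1.61 ± 0.20) and Ccnd1 (1.16 ± 0.17). The median difference was 1.10, 10 rose when adjusted over the list alone, and camera gave adjusted p = 1.60e-05. Of the 33 lists past the set test it alone held with an estimated correlation, at adjusted p = 0.0274. Its estimated correlation was -0.00197, against 0.469 for the cell cycle list, so the estimate weakened this list's test less. The 7 members that did not pass were Dusp6 (0.24), Spry1 (0.23), Etv5 (0.59), Epha2 (0.45), Fosl1 (1.10), Spry4 (-0.41) and Ier3 (-0.45). With Eif2s3y as a covariate 6 of its genes rose. ErbB receptors and ligands rose in 3 of 13 cases, Erbb3 (1.11 ± 0.14) and Ereg (3.67 ± 0.54) among them, and Egfr fell (-1.81 ± 0.34, adjusted p = 0.00103). Members had a median difference of 0.57, 3 rose and 1 fell when adjusted over the list alone, and the set test gave camera adjusted p = 0.0136, and adjusted p = 0.252 with an estimated correlation. Egfr has 7 probe sets of which 3 fell, and when normal lung 4 or 6 was left out another became the brightest, with a difference up to -0.48 and adjusted p up to 0.116. Both with Eif2s3y as a covariate and without normal lungs 2 and 4, 2 ErbB genes rose and 0 fell, so the Egfr call was lost there too.

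Notch and TGF-beta lists were lower alongside the endothelial list, of which 23 of 24 genes fell (median -2.83). Notch pathway genes fell in 9 of 13 cases, with Notch4 (-2.48 ± 0.15) and Hey1 (-3.42 ± 0.29), both known from vessels. The members' median was -1.08, and 11 fell when adjusted over the list alone, with camera adjusted p = 4.00e-05, and adjusted p = 0.145 with an estimated correlation. TGF-beta and BMP genes fell in 11 of 21, with Ltbp4 (-3.02 ± 0.14) and Smad6 (-3.46 ± 0.21), and 3 rose, including Id2 (2.79 ± 0.26). For this list the median was -0.70, 4 rose and 11 fell when adjusted over the list alone, and the set test gave camera adjusted p = 0.00801, and adjusted p = 0.252 with an estimated correlation. Acvrl1 and Eng, which fell, belong to both the TGF-beta and the endothelial list. The fetal lung list had 5 of 13 genes up, with Sox4 (1.71 ± 0.20), and 2 down, Igf2 (-1.77 ± 0.19) and Sox11 (-2.95 ± 0.41). These members had a median of 0.54, and 6 rose and 2 fell when adjusted over the list alone, with camera adjusted p = 0.0364, and adjusted p = 0.155 with an estimated correlation. The fetal list lost its set call under both scalings and without normal lung 4. The Wnt list had 2 of 15 members higher and 7 lower (median -0.50, camera adjusted p = 0.136), the falls including Axin2 (-1.58 ± 0.19) and the rises Dkk2 (2.86 ± 0.43). In the fry test it moved down (adjusted p = 1.12e-04), and its mean in all 6 tumours lay below every normal lung. After quantile normalization and after median centring 4 members were higher and 7 lower.

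Epithelial junction genes rose and detoxifying enzymes fell. Of 24 junction and keratin genes 14 rose, with Epcam (2.30 ± 0.18), Spint1 (1.58 ± 0.14) and Krt18 (2.36 ± 0.34), and Tjp1 fell (-0.81 ± 0.13). In this list 16 rose and 1 fell when adjusted over the list alone, with a median of 0.95, and the set test gave camera adjusted p = 1.65e-07, and adjusted p = 0.143 with an estimated correlation. Xenobiotic metabolism genes fell in 12 of 20 cases, with Fmo1 (-4.06 ± 0.34), Cyp2e1 (-3.29 ± 0.40) and Cyp2b10 (-3.22 ± 0.43). Across the list the median was -2.03, and 1 rose and 15 fell when adjusted over the list alone, with camera adjusted p = 1.10e-04, and adjusted p = 0.145 with an estimated correlation. Of these falls 4, Cyp4b1, Cyp2f2, Aldh1a1 and Cbr2, are also members of the club cell list, of which 9 of 14 genes fell. Normal lungs 2 and 4 carried liver transcripts and Cyp2e1 is abundant in liver, and without these lungs 9 genes of the list fell, Cyp2e1 still among them. Fatty acid synthesis genes rose in 5 of 14, with Me1 (2.31 ± 0.18) and Fasn (1.30 ± 0.24), and Elovl5 fell (-0.63 ± 0.16), though not under median centring. The set test gave camera adjusted p = 0.0351, and adjusted p = 0.405 with an estimated correlation, the median was 0.34, and 5 rose and 1 fell when adjusted over the list alone. The set call was lost under quantile normalization and median centring, and without tumour 1 or 5. Interferon response genes fell in 10 of 17, with Ifit2 (-1.17 ± 0.20), and Mx1 rose (1.45 ± 0.42). Members had a median difference of -0.88, 1 rose and 11 fell when adjusted over the list alone, and the set test gave camera adjusted p = 0.0132, and adjusted p = 0.472 with an estimated correlation. The number falling was 6 under median centring, and 4 with none rising both without normal lungs 2 and 4 and with Eif2s3y as a covariate. Tumour 2 had an interferon list mean of 9.53, above the highest normal lung at 9.37. Chemokines rose in 7 of 20, with Ccl6 (1.87 ± 0.22) and Cxcl5 (2.83 ± 0.59), and 2 fell. The members' median was 0.68, and 7 rose and 2 fell when adjusted over the list alone, with camera adjusted p = 0.00724, and adjusted p = 0.308 with an estimated correlation. With Eif2s3y as a covariate 3 chemokines rose, and without normal lungs 2 and 4 8 rose and none fell.

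The NRF2 target list had 4 of 16 members higher and 3 lower (median 0.17, camera adjusted p = 0.305). Cholesterol synthesis had 1 of 15 members higher and 2 lower (median 0.05, camera adjusted p = 0.504). The unfolded protein response had 3 of 15 members higher and 3 lower (median -0.02, camera adjusted p = 0.707), its camera direction being up and its median negative. Matrix remodelling had 3 of 20 members higher and 7 lower (median -0.65, camera adjusted p = 0.393, fry adjusted p = 0.0189 downwards). The p53 target list had 6 of 18 members higher and 2 lower (median 0.32, camera adjusted p = 0.0964), the rises including Ccng1 (1.63 ± 0.21) and the falls Sesn1 (-1.61 ± 0.14). The immediate early list had 3 of 16 members higher and 6 lower (median -0.40, camera adjusted p = 0.24, fry adjusted p = 0.00985 downwards). The heat shock list had 1 of 12 members higher and 4 lower (median -0.30, camera adjusted p = 0.393). The balance of several of these counts depended on scaling. Members higher and lower after quantile normalization, then after median centring, were 2 and 5 then 4 and 1 for the unfolded protein response, 0 and 4 then 3 and 3 for heat shock, 4 and 4 then 5 and 2 for NRF2 targets, and 2 and 2 then 3 and 1 for cholesterol synthesis. Median heat shock differences were then -0.43 and -0.11, and those of the unfolded protein response -0.16 and 0.17. Without normal lungs 2 and 4, 2 and 1 members of the unfolded protein response, 4 and 1 NRF2 targets and 1 and 6 immediate early genes were higher and lower. Circadian clock genes fell in 7 of 15 cases, with Hlf (-1.84 ± 0.28). For this list the median was -0.74, 1 rose and 9 fell when adjusted over the list alone, and the set test gave camera adjusted p = 0.0186, and adjusted p = 0.308 with an estimated correlation.

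**Figure D4:**
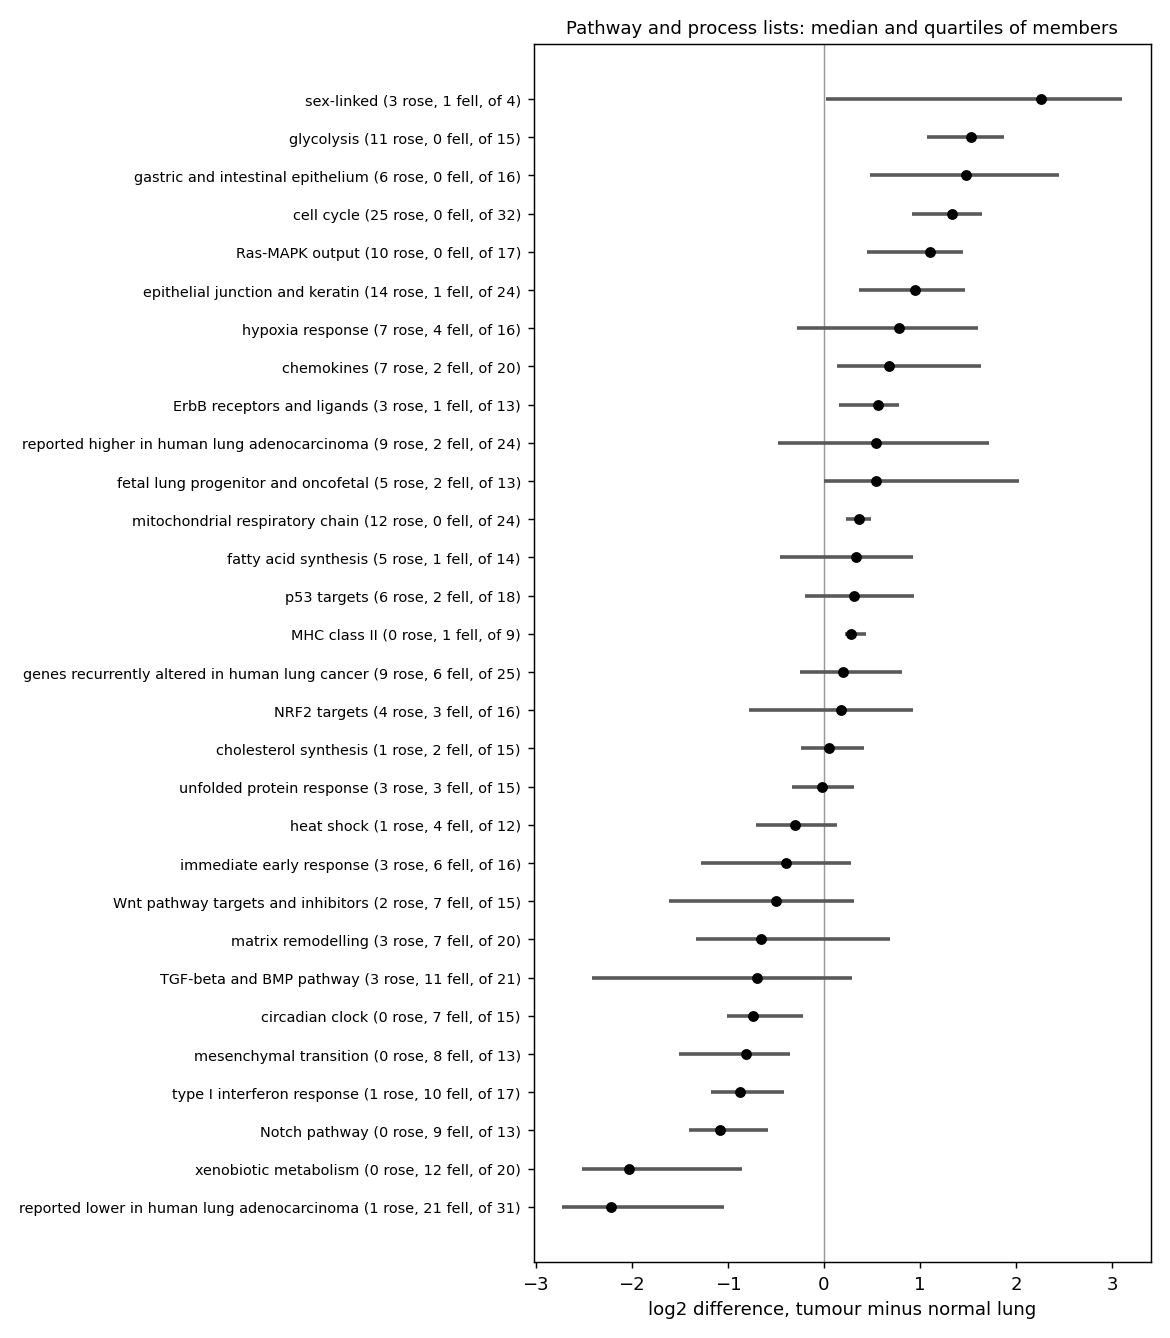
Median (point) and quartiles (line) of the log2 differences of the measured members of each pathway, process and handling list, tumour minus normal lung, 6 arrays each. Glycolysis has a median of 1.53 and xenobiotic metabolism one of -2.03.

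The series title names a comparison with human non-small cell lung cancer, so genes generally reported for human lung adenocarcinoma were examined; no human data were used here. Of 24 measured genes reported higher, 9 rose (37.5%), with Hmgb3 (2.03 ± 0.14), Golm1 (2.57 ± 0.21) and Tmprss4 (1.70 ± 0.31), and 2, Hs6st2 and Uchl1, fell. These members had a median of 0.54, and 10 rose and 3 fell when adjusted over the list alone, with camera adjusted p = 0.00995, and adjusted p = 0.221 with an estimated correlation. Random lists matched on mean signal gave 12.1% on average (one-sided permutation p = 0.001, 10000 lists). Of 31 genes reported lower, 21 fell (67.7%), with Lyve1 (-2.60 ± 0.21), Grk5 (-1.88 ± 0.16) and Stxbp6 (-2.45 ± 0.22), and Fabp4 rose. In this list 1 rose and 26 fell when adjusted over the list alone, with a median of -2.21, and the set test gave camera adjusted p = 1.76e-10, and adjusted p = 0.145 with an estimated correlation. Of the 21 falls 12 are members of the cell type lists above, 5 endothelial, 4 type I, 2 fibroblast and 1 mesothelial, so this count in part repeats theirs. Random lists, matched on signal and not on cell type, gave 19.5% (one-sided permutation p = 0.0001, the smallest 10000 lists can give).

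Genes recurrently altered in human lung cancer moved in both directions. Of 25 measured, 9 rose and 6 fell, 9 rose and 6 fell when adjusted over the list alone, and camera gave adjusted p = 0.125. On balance the list moved up in the fry test (adjusted p = 0.00875), and its mean in all 6 tumours lay above every normal lung. Met, a receptor kinase, rose from 1099 ± 139 to 4350 ± 1895 (1.87 ± 0.23), Myc rose (2.16 ± 0.44) and Ros1 rose (2.98 ± 0.68). Stk11, a tumour suppressor kinase, fell (-0.58 ± 0.13), a call lost with the mean of its probe sets, and Dlc1 fell (-1.49 ± 0.24). Cdkn2a, which encodes cell cycle inhibitors, rose (1.04 ± 0.33, adjusted p = 0.0327), a call lost without normal lung 1, 2, 4 or 6 or tumour 1, 2, 4 or 5 (adjusted p up to 0.0759). Tgfbr2 did not pass (-0.28 ± 0.13), though it did after quantile normalization. Trp53 was not analysed here.

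Tumours differed more among themselves than normal lungs did. The root mean squared distance of an array from the mean of the other 5 of its group was 0.544 ± 0.0544 log2 units in normal lungs and 0.659 ± 0.0716 in tumours (SD, n = 6 each). The difference was 0.115 (two-sided permutation of the per-array distances, p = 0.013). Distances were not recomputed for each assignment, and those within a group depend on each other, so this p is approximate. The tumours were mixed for Xist and Eif2s3y and the normal lungs were not, and the share of this in the spread was not tested. The SD of a probe set was larger in tumours for 63.3% of probe sets. Without normal lungs 2 and 4, a setting chosen after seeing the data, the spread between arrays differed by 0.0997 (permutation of the distances, p = 0.0667).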

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

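Tests of explanations in these paragraphs were all chosen after the pattern had been seen. An array stood far from the other 5 of its group in 17 of 180 groups of values examined, where chance gives about 9.

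Among genes, normal lung 4 was highest of its group for Arg1 (log2 8.65, next 6.89) and Mmp12 (8.26, next 7.01). Bcl2l15 was highest in normal lung 5 (5.38) and lowest in tumour 6 (6.97, next 8.54). Tmem100 was highest in tumour 4 (10.81, next 7.76).

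Among list means, normal lung 1 stood highest for neutrophil genes (13.51, next 9.67), glycolysis (10.64) and matrix remodelling (9.14). Normal lung 2 stood highest for adipocyte genes (8.35, next 6.99), fatty acid synthesis (11.35), NRF2 targets (10.996) and circadian clock genes (9.19). Normal lung 3 was highest for ciliated genes (9.62), and normal lung 6 for natural killer genes (8.51, next 7.77). Tumour 5 was highest for the unfolded protein response (11.91), and tumour 2 for the interferon response (9.53, next 8.60). The actin 3' to 5' ratio was highest in tumour 1 (1.32, next 1.19).

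The normal lungs all carried Xist without Eif2s3y and 4 of 6 tumours the reverse, so sex of the animals could account for part of the calls. Genes called 2-fold in the 4 tumours with Eif2s3y against normal lungs 1 to 3 numbered 2049. In the 2 tumours with Xist against normal lungs 4 to 6, which share no array with the first set, 97.9% had the same sign, with a median difference of 1.62 against 1.81. Sex as the whole cause of the calls is therefore ruled out by these values. Sex effects on single genes stay open, since no normal lung carried Eif2s3y.

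Cell type lists moved apart, and a simple rise in epithelial share was examined as a cause. Dilution of every other cell type alike predicts that macrophage and endothelial lists shift equally. In each tumour the macrophage list lay above the endothelial list by 3.07 or more log2 units after subtracting normal means. For these lists this argues against equal dilution. The lists were picked after their shifts were seen, and whether epithelium also makes some macrophage list genes was not tested. Normal pieces that held more airway, large vessel and vein could produce the falls in ciliated, smooth muscle and cardiac lists, which averaged -2.35 or lower. Sampling of the pieces and absence of these cells from tumours cannot be told apart, because the pieces differ with the groups.

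Tumours 2 and 6 had the lowest type II and the highest gastric and intestinal means of the 6 tumours. More surrounding lung would bring the gastric list towards normal lungs, but the lower of these tumours lay 2.59 log2 units above the highest normal lung. Carry-over of stomach RNA cannot be told apart in either tumour. In tumour 2 Gkn1 at 101, Gkn2 at 1170 and Tff1 at 1774 exceeded every normal lung, while Gkn1 stayed below that array's median of 126.5. Gkn3 in tumour 2, at 230.8, lay within the range of normal lungs. In tumour 6 Gkn1 was at 24.1, near the floor, and Tff1 at 904.8, where its level of 978 to 1412 in normal lungs would hide a small share, so neither excludes it. Gkn2 was at 3550 there against 91.8 or less in normal lungs, but also at 342, 18970 and 1828 in tumours 3, 4 and 5, so it does not mark this pair. Gkn3 at 53.55 in tumour 6 lay below every normal lung (124 to 249), which goes against carry-over, though this level too would hide a small share. A hypothesis is that tumours 2 and 6 may have lost type II features together with gaining a gastric programme, and the same 2 of 6 would top both orders by chance with probability 0.0667, too large to decide.

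The real grouping gave more calls than any other split examined. The 100 splits were the real one, put in on purpose, and others drawn from all splits of the 12 arrays. Only the real one reached as many calls, and 1 in 100 is the smallest share this comparison can give. The other splits mix tumours with normal lungs, so the group difference widens the spread within their groups and lowers their calls. They therefore do not give the number of calls expected by chance. The real counts were 4529 and 6279 probe sets and 846 and 1911 genes, against at most 31 probe sets and 15 genes in either direction of any other split drawn. The number of lists past the set test was 33 against at most 27, so calls of lists at the preset correlation also occur in splits that mix the groups.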

How the results depend on the processing

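Of the named genes past the threshold, Eif2s3y, Kdm5d, Uty and Xist changed sign under an alternative, and the lists past the set test kept the sign of their median. Medians of lists not past it changed sign for MHC class II, sex-linked, unfolded protein response, basal, cholesterol synthesis, erythroid and neuroendocrine genes. Median centring turned the balance of calls, from 41.9% to 61.9% higher. Of the 2757 genes called 2-fold, the fewest to keep their sign were 2737, with the brightest probe set without shared-suffix IDs; 2748 did without the tumours with Eif2s3y, 2751 without normal lungs 2 and 4, 2755 with offset 1, 2756 with the mean of probe sets, and 2752 to 2756 without any 1 array. Quantile normalization, median centring and the Eif2s3y covariate kept all 2757. Median centring raised the probe sets higher in tumours to 7431. Lists higher in the set test numbered 8 with only probe sets above the median brightness, where fewer genes are tested, and with camera at an estimated correlation 1 was higher and 0 lower. Leaving out 1 array gave 3839 to 4858 probe sets higher in tumours, 5617 to 6321 probe sets lower in tumours, 793 to 898 genes at least 2-fold higher in tumours, 1828 to 1961 genes at least 2-fold lower in tumours, and 14 to 15 lists higher and 17 to 18 lower. The spread between arrays then differed by 0.0861 to 0.150. Other settings were chosen after seeing the data. Without normal lungs 2 and 4, 3003 probe sets were higher and the spread difference was 0.0997 (permutation of the distances, p = 0.0667, fewer arrays). With Eif2s3y as a covariate 2603 were higher and 4069 lower; the cause was not tested. Without the tumours with Eif2s3y signal the differences of Eif2s3y (-0.43), Uty (-0.24) and Xist (0.26) reversed, because the tumours that carried the Y-linked signal were removed. The Kdm5d difference was -1.23 there, on another probe set that had become the brightest. On the Kdm5d probe set of the main fit tumours 4 and 6 were at 24.01 and 13.28, within the 2.109 to 48.15 of normal lungs. Same-number correlations of deviations were -0.0178 to 0.0217, which gave no sign that the replicate numbers pair the arrays. Eif2s3y was at 740 or more in tumours 1, 2, 3 and 5 and at 27.4 or less in every normal lung. This argues against those tumours sharing an animal with any of the normal lungs, and leaves tumours 4 and 6 open. With the replicate block, 3969 probe sets were higher and 5646 lower, and 851 and 1889 genes 2-fold. Signal near the floor limits dim genes, as 13.4% to 15.1% of probe sets lay under the offset.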

Other observations

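Some single genes differed widely between tumours. Dlk1, an imprinted growth regulator, was at 10570, 3390, 20200 and 7903 in tumours 1, 3, 4 and 6, and at 121 and 109 in tumours 2 and 5, against 61.1 to 125 in normal lungs. Meg3, a neighbouring imprinted RNA, reached 32370, 26890, 21400 and 12410 in tumours 1, 3, 4 and 5, 3078 in tumour 6 and 259 in tumour 2, against 525 to 718 in normal lungs. Krt20, an intestinal keratin, was at 7489 and 7535 in tumours 2 and 6 and at 75.4 or less on every other array. Anxa10 (9131 and 2702) and Hmga2 (3629 and 3090) were highest in the same pair. Bpifa1 ranged from 739 to 54390 among tumours. These genes were chosen after their values were seen, and no test was run on them.

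Liver transcripts were present in some normal lungs. Alb, the albumin gene, was at 13840 and 13720 in normal lungs 2 and 4, 2069 in normal lung 6 and 508 or less in the other 3. Serpina1b was at 3027 and 2241 in normal lungs 2 and 4. The mean log2 signal of 17 further liver genes, listed after Alb had been seen, was 8.02 and 9.11 in normal lungs 2 and 4, 7.15 in normal lung 6, 6.24 to 6.39 in the other 3 and 5.79 to 6.42 in tumours. Alb was also at 2451, 4901 and 2119 in tumours 4, 5 and 6, where Serpina1b was at 8.14, 3.79 and 144.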
